A study of Methylobacter tundripaludum 31/32 and Methylobacter tundripaludum 21/22 with 32 samples.

How the data were processed

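RNA was sequenced from cultures of Methylobacter tundripaludum 31/32 (20 libraries) and 21/22 (12 libraries), with 1 count file per library. Per the labels' protocols, cells were fixed with phenol in ethanol and lysed by bead beating, and the RNA was treated with DNase and column-purified. A commercial provider prepared the cDNA libraries and sequenced them as Illumina paired-end reads. Whether the libraries keep strand, and how ribosomal RNA was handled, is not given in the sources used here. The protocol for oxygen levels in the labels describes the oxygen experiment on 31/32 only.

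The deposited values are whole-number counts of reads per gene ID, not normalized. The submitters' processing notes name BWA 0.7.12, SAMtools 1.2-232, HTSeq, DESeq2 1.2.10 and R 3.3.0 without their roles. The genome build and the annotation are not given in the sources used here, and no reference was used. The 31/32 files list 4604 IDs and the 21/22 files 4174, of which 482 and 2 were at 0 in every library of the strain. Reads of genes with near-identical copies or of overlapping and antisense genes may be split or lost in such counting, and these could not be marked without an annotation. The closing lines of each file, which name no gene (reads outside genes, ambiguous, of low alignment quality, not aligned, aligned at several places), were kept out of library sizes and tests. They made up 17.4% to 84.1% of the reads.

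Groups and replicate numbers came from the labels, which call the replicates biological and give no date, batch or shared culture. The p-values rest on the spread between these replicates, estimated per gene over all groups of a fit. Replicates were compared with each other: a chi-square of their counts per degree of freedom was 4.35 to 317, so no pair was alike within sampling noise. The Pearson r of their log2 CPM across genes was 0.973 to 0.999. In the oxygen experiment this r was 0.973 to 0.990 at low and 0.997 to 0.998 at high oxygen, and 1 spread per gene served both.

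Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM scaling, filterByExpr by group, robust dispersion estimates, and the quasi-likelihood F test with 1 mean per group and Benjamini-Hochberg adjustment over all genes tested. One fit covered the 16 libraries of the oxygen experiment (3947 genes tested, 8 residual degrees of freedom, common biological coefficient of variation 0.134), one the 4 libraries of the nitrogen experiment (3954 genes, 2 degrees of freedom, 0.0356) and one the 12 libraries of 21/22 (4169 genes, 6 degrees of freedom, 0.0775). A fit of all 20 libraries of 31/32 (3958 genes) served only to compare the 2 experiments. Interactions were tested as differences of 2 log2 fold changes in the same fits. The standard error of a log2 fold change is its size divided by the square root of the F statistic, which is approximate. Genes with an adjusted p under 0.05 are called.

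The IDs named for a comparison are at most 2 that rose and 2 that fell: those with the highest and lowest log2 fold change among called IDs with a mean of at least 8 CPM in the higher group and both libraries of one group above both of the other. No claim is made that this naming rule was fixed before the data were examined. For interactions, which are differences of 2 log2 fold changes, its condition on the libraries was not applied. The fits and the alternatives were fixed before the data were examined, except 4 alternatives added after seeing the data. Among these were leaving out 2 libraries of low alignment quality and, separately, leaving out the tundrinone- libraries. Another thinned every library to the smallest total of its fit (equal depth). The last was a block for the replicate number in the low-oxygen groups alone. Tests of 24 gene lists and their repeat with an estimated correlation were fixed too but not run, because the files do not pair IDs with product names.

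The alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0 in place of edgeR, no filter on low counts, removal of the 10 most abundant genes, only the 2 groups of a comparison, a replicate block, leaving out each library in turn, and all 31/32 libraries in 1 fit. A library left out leaves its group with 1 library, which is assumed to vary like the other groups. The procedure was tested on simulated counts made from the means and library sizes of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. For the wild-type oxygen comparison on nitrate (3946 genes) 97% and 98% of these were recovered and 2.99% of the calls were false. For the nitrogen experiment (3953 genes) the values were 98%, 100% and 7.91%, and for the wild type of 21/22 (4169 genes) 98%, 100% and 5.26%. In these simulations all other genes were unchanged and each gene had 1 spread in all groups. They do not cover the wider spread of the low-oxygen replicates or the difference these share by replicate number. Correlations of fold changes were computed for the 65 pairs of comparisons within a strain that share no library, except in the section on shared controls. Figures were drawn with python 3.11.15.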

Results

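Gene expression was measured by RNA sequencing in Methylobacter tundripaludum, a bacterium that grows on methane, in the strains 31/32 and 21/22. The series is about nitric oxide, quorum sensing (signalling by cell density) and the secondary metabolite tundrenone in the response to low oxygen. There were 32 libraries in 16 groups of 2 biological replicates. An oxygen experiment on 31/32 set the wild type beside hcp/hcr-, a deletion in hcp (hybrid cluster protein, an enzyme that reduces nitric oxide) and hcr (its reductase), on nitrate or ammonia as the nitrogen source and at high or low oxygen. A nitrogen experiment on 31/32 compared nitrate and ammonia in the wild type. In 21/22, the wild type, a quorum sensing mutant (qs-) and a mutant in tundrenone production (tundrinone-, as the labels spell it) were each grown on nitrate and on ammonia. In the oxygen experiment, high-oxygen cultures were collected 1 h after the methane and air atmosphere was renewed, and low-oxygen cultures 24 h after a change to methane and dinitrogen, so oxygen level and time to collection differed together in every oxygen comparison.

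Counts assigned to genes ranged from 7258303 to 58659888 per library in the oxygen experiment, from 33093264 to 44759613 in the nitrogen experiment and from 9666615 to 49511985 in 21/22. One ID took 8.73% to 30.4% of the gene counts of each library in the oxygen experiment (T449DRAFT_2095) and one 10.2% to 29.2% in 21/22 (2563531019). Reads that were not aligned made up 41.5% to 63.0% of the reads in the 4 tundrinone- libraries and 0.217% to 3.47% in the 8 wild-type and qs- libraries of 21/22. Low alignment quality removed 52.3% of the reads (95% exact binomial interval 52.28% to 52.30%) in hcp/hcr- nitrate low oxygen replicate 2 and 71.0% (71.02% to 71.05%) in hcp/hcr- ammonia low oxygen replicate 2. These intervals cover counting error only.

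**Figure D1:**
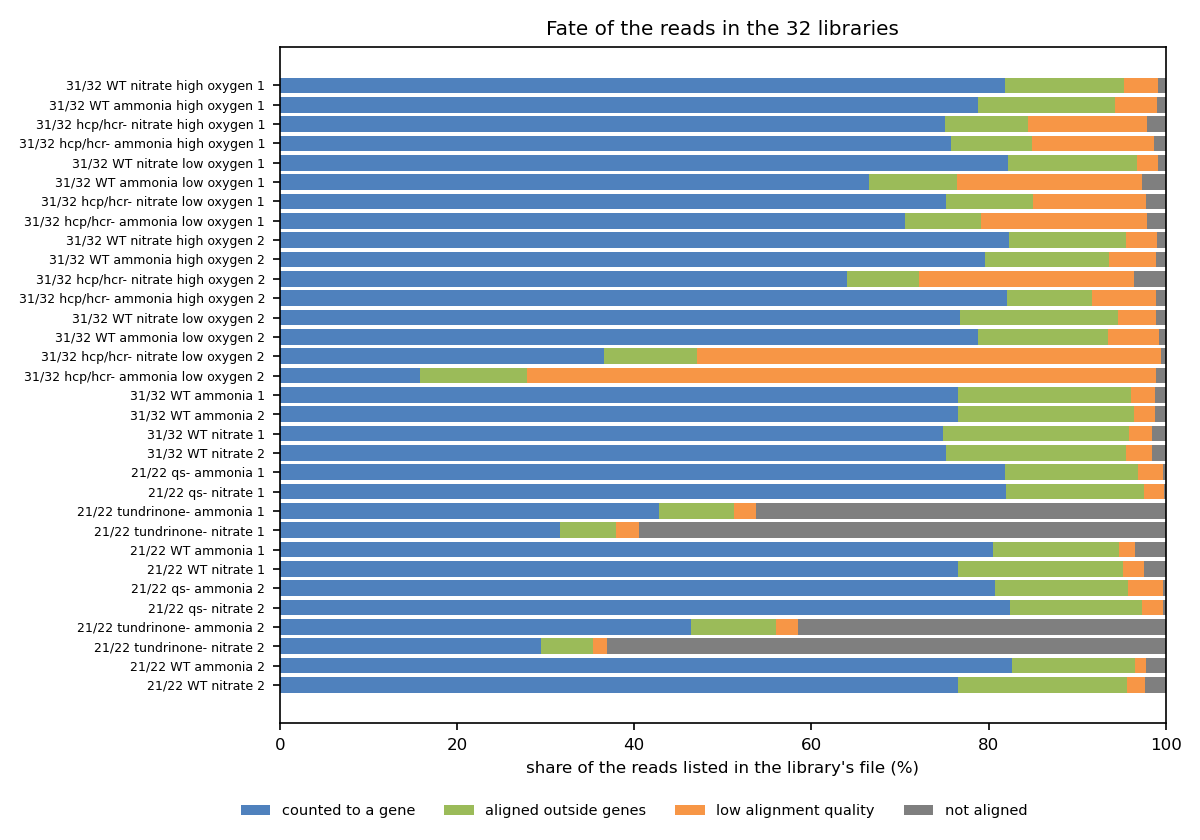
Share of the reads listed in each library's file (x axis, %) that were counted to a gene, aligned outside genes, set aside for low alignment quality or not aligned, for each of the 32 libraries (y axis, 1 bar per library). In the 4 tundrinone- libraries 41.5% to 63.0% of the reads were not aligned, and in 2 hcp/hcr- low-oxygen libraries low alignment quality took 52.3% and 71.0%.

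The files do not pair gene IDs with gene names, so no function is given for any ID, and the deleted genes could not be looked up by name to check the mutant labels. Among IDs lower in every library of a mutant than in every wild-type library, the one with the highest ratio of the lowest wild-type to the highest mutant CPM was looked up after the values were seen. These ratios were 2.45 for hcp/hcr-, 37.3 for qs- and 5.87 for tundrinone-. T449DRAFT_2451 had 1 to 19 counts in the 8 hcp/hcr- libraries and 168 to 35474 in the 8 wild-type libraries of the oxygen experiment. In 21/22, 2563530944 had 19 to 35 counts in the 4 qs- libraries and 1194 to 4271 in the 4 wild-type libraries, and 2563533633 had 48 to 225 counts in the 4 tundrinone- libraries and 2919 to 7809 in the wild type. Whether these are the targeted genes is not known from the files. Below, CPM are counts scaled to the TMM-adjusted library size, as mean ± SD of 2 libraries, and a gene called higher or lower has an adjusted p under 0.05.

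The first question was how the wild type of 31/32 differed between oxygen levels on nitrate. T449DRAFT_2451 rose from 6.51 ± 1.34 CPM at high oxygen to 693 ± 20.7 CPM at low oxygen, a log2 fold change of 6.73 (SE 0.51, n = 2 per group, adjusted p = 6.61e-07), and T449DRAFT_4040 from 35.1 ± 0.757 to 1996 ± 148 CPM (log2 fold change 5.83, SE 0.16, adjusted p = 1.54e-10). T449DRAFT_4210 fell from 363 ± 0.324 to 11.2 ± 0.272 CPM (log2 fold change -5.01, SE 0.26, adjusted p = 1.95e-08), and T449DRAFT_3349 from 8.62 ± 0.567 to 0.323 ± 0.276 CPM (log2 fold change -4.58, SE 0.45, adjusted p = 2.56e-06). Of 3947 genes tested, 1289 were higher and 1494 lower at low oxygen by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1313 of the 2783 differed at least 2-fold. The median absolute log2 fold change over all genes tested was 0.69.

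On ammonia, the wild type showed a smaller difference between oxygen levels. T449DRAFT_3782 rose from 107 ± 17.6 to 5989 ± 1759 CPM (log2 fold change 5.80, SE 0.30, adjusted p = 5.08e-08), and T449DRAFT_2451 rose here too, from 13.3 ± 0.0801 to 452 ± 189 CPM (log2 fold change 5.09, SE 0.47, adjusted p = 5.53e-06). T449DRAFT_3549 fell from 371 ± 23.0 to 16.6 ± 0.687 CPM (log2 fold change -4.48, SE 0.12, adjusted p = 3.68e-10), and T449DRAFT_1744 from 19.3 ± 1.04 to 0.855 ± 0.228 CPM (log2 fold change -4.51, SE 0.37, adjusted p = 1.05e-06). In all 1150 genes were higher and 1282 lower at low oxygen, 808 of them at least 2-fold, with a median absolute log2 fold change of 0.52. Across the 3947 genes the fold changes on nitrate and ammonia had a Pearson r of 0.644 and a Spearman rho of 0.645. Genes are not independent replicates, and this was 1 of 65 such relations computed. Of 1901 genes called on both nitrogen sources, 753 were higher and 907 lower in both, where independent lists of these sizes would share 376 and 485. The oxygen effect itself differed between the nitrogen sources in 1921 genes (877 of them with a higher log2 change on nitrate, the rest with a lower one). By the naming rule, T449DRAFT_4195 had the most positive difference of log2 fold changes (5.77, SE 0.16, adjusted p = 1.22e-09): it rose 3.66-fold at low oxygen on nitrate and fell 14.9-fold on ammonia. That count was 1187 at equal depth, an alternative added after the data were seen.

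In hcp/hcr- on nitrate the oxygen comparison gave the most calls of the 4. T449DRAFT_4630 rose from 9.23 ± 1.15 to 478 ± 244 CPM (log2 fold change 5.69, SE 0.40, adjusted p = 1.91e-07), and T449DRAFT_4040 from 33.9 ± 0.146 to 1710 ± 291 CPM (log2 fold change 5.66, SE 0.16, adjusted p = 9.59e-11), close to its wild-type levels. T449DRAFT_3461 fell from 34.6 ± 0.152 to 0.336 ± 0.0384 CPM (log2 fold change -6.64, SE 0.27, adjusted p = 1.02e-09), and T449DRAFT_2034 from 28.3 ± 3.37 to 0.960 ± 0.564 CPM (log2 fold change -5.01, SE 0.34, adjusted p = 5.98e-08). There were 1431 genes higher and 1516 lower at low oxygen, 1685 of them at least 2-fold. Across genes the fold changes followed those of the wild type on nitrate (Pearson r 0.848), and 95.6% of the 2369 genes called in both went the same way. The genotypes still differed in their oxygen effect in 1250 genes (620 with a higher log2 change in the mutant and 630 with a lower one). T449DRAFT_3942 rose 27.5-fold in the mutant and fell 3.38-fold in the wild type (difference of log2 fold changes 6.54, SE 0.24, adjusted p = 1.23e-08). T449DRAFT_0964 fell 18.9-fold in the mutant and rose 1.37-fold in the wild type (-4.70, SE 0.24, adjusted p = 1.38e-07). The 1250 became 662 at equal depth, 833 without wild-type nitrate high oxygen replicate 2, and 1976 with the replicate number as a block in the low-oxygen groups.

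In hcp/hcr- on ammonia few genes differed between oxygen levels. T449DRAFT_3180 rose from 209 ± 18.8 to 710 ± 115 CPM (log2 fold change 1.76, SE 0.32, adjusted p = 0.0264), and T449DRAFT_4122 from 7.74 ± 1.95 to 26.2 ± 2.54 CPM (log2 fold change 1.75, SE 0.29, adjusted p = 0.0157). T449DRAFT_3100 fell from 174 ± 42.2 to 90.7 ± 8.97 CPM (log2 fold change -0.94, SE 0.18, adjusted p = 0.0299), and T449DRAFT_3596 from 8.47 ± 0.386 to 4.47 ± 1.39 CPM (log2 fold change -0.84, SE 0.17, adjusted p = 0.0357). These 4 calls were lost when only the 4 libraries of the comparison were fitted and when either high-oxygen library or low oxygen replicate 2 was left out. In all 32 genes were higher and 31 lower, 6 of the 63 at least 2-fold, and the median absolute log2 fold change over all genes was 0.15, against 0.52 in the wild type on ammonia. The 188 genes that rose and the 297 that fell at least 2-fold in both wild-type comparisons had median log2 fold changes of 0.11 and -0.09 here, and of 2.06 and -2.21 in hcp/hcr- on nitrate. The difference between genotypes in the oxygen effect on ammonia passed the test in 1863 genes (1016 with a higher log2 change in the mutant and 847 with a lower one), with T449DRAFT_3782 at -5.69 (SE 0.37, adjusted p = 1.14e-06) and T449DRAFT_3952 at 4.52 (SE 0.31, adjusted p = 1.14e-06). T449DRAFT_4040, named above for nitrate, had a difference of -2.65 (SE 0.19, adjusted p = 1.4e-06).

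The count of 63 depended on the setting more than any other count of the oxygen experiment. It was 212 with DESeq2, 35 without the 2 libraries of low alignment quality, 18 at equal depth and 540 with a block for the replicate number in the low-oxygen groups (21 of these at least 2-fold). It was 0 when edgeR's quasi-likelihood test was fitted to the 4 libraries alone, where 592 of 3944 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.0593. Leaving out high oxygen replicate 1, high oxygen replicate 2, low oxygen replicate 1 or low oxygen replicate 2 of this comparison gave 5, 2, 280 and 7 genes. The number of genes of the ammonia interaction at equal depth was 1230.

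**Figure D2:**
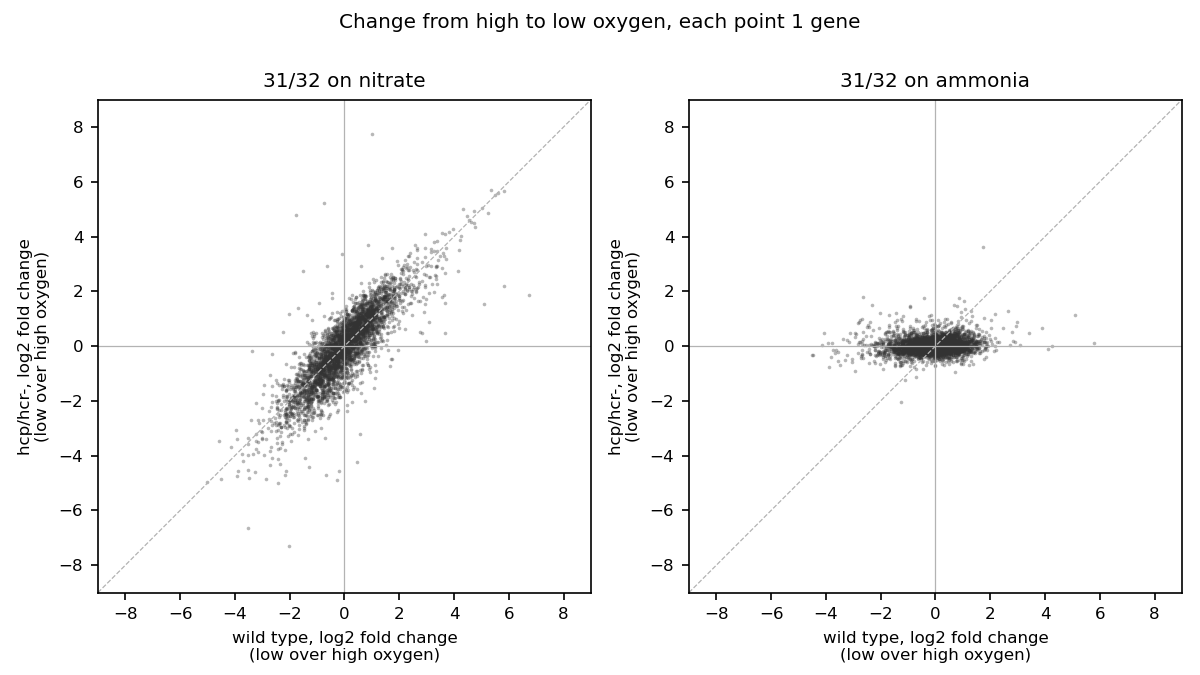
Log2 fold change from high to low oxygen in the wild type (x axis) and in hcp/hcr- (y axis) for each of the 3947 genes tested, on nitrate (left) and on ammonia (right), with 1 point per gene and a dashed line where both are equal. On nitrate the points lie along the dashed line (Pearson r 0.848 across genes), and on ammonia they spread along the x axis, with a median absolute change of 0.52 in the wild type and 0.15 in hcp/hcr-.

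The hcp/hcr- mutant was compared with the wild type in each of the 4 conditions. T449DRAFT_2026 was higher in the mutant in all of them, from 1.74 ± 0.299 to 519 ± 0.202 CPM on nitrate at high oxygen (log2 fold change 8.22, SE 0.16, adjusted p = 2.03e-11). Its log2 fold changes were 7.41 (SE 0.15) on nitrate at low oxygen, 7.16 (SE 0.15) on ammonia at high oxygen and 7.47 (SE 0.15) on ammonia at low oxygen. T449DRAFT_2027 rose with it, to 673 ± 17.1 CPM on nitrate at high oxygen (log2 fold change 9.14, SE 0.26, adjusted p = 1.41e-10). In the nitrogen experiment, however, the wild type on ammonia had 198 and 226 CPM of T449DRAFT_2026 and 171 and 172 CPM of T449DRAFT_2027 (without TMM scaling). At least 4-fold differences in all 4 conditions were seen in 45 genes that were higher in the mutant and 1 that was lower. At low oxygen T449DRAFT_2451 was lower in the mutant, at 0.686 ± 0.690 against 693 ± 20.7 CPM on nitrate (log2 fold change -10.26, SE 0.65, adjusted p = 4.92e-07) and at 1.06 ± 0.796 against 452 ± 189 CPM on ammonia (-9.17, SE 0.63, adjusted p = 5.14e-07).

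On nitrate, 906 genes were higher and 928 lower in hcp/hcr- at high oxygen, 427 of them at least 2-fold, with T449DRAFT_3942 (4.61 ± 0.0425 against 137 ± 3.84 CPM) and T449DRAFT_1208 (31.1 ± 4.42 against 769 ± 4.16 CPM) as the IDs that fell the most by the naming rule. At low oxygen 776 were higher and 873 lower, 400 of them at least 2-fold. T449DRAFT_2014 led these with 3608 ± 303 against 3.54 ± 1.06 CPM (log2 fold change 10.01, SE 0.24, adjusted p = 7.05e-11). The wild type on ammonia of the nitrogen experiment had 277 and 315 CPM of it without TMM scaling. The 1834 and 1649 genes became 3064 and 672 when only the 2 groups were fitted (the 672 with 60.6% higher, against 47.1%), and 1166 and 1070 at equal depth.

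On ammonia the genotypes differed in more genes. A wrong oxygen label on the hcp/hcr- ammonia libraries labelled high oxygen could not be excluded, and the high-oxygen values rest on that label. At high oxygen 1378 were higher and 1429 lower in the mutant, 1319 of them at least 2-fold. T449DRAFT_4154 (10.1 ± 0.474 against 1846 ± 315 CPM, log2 fold change -7.52, SE 0.48, adjusted p = 1.52e-07) and T449DRAFT_4153 (4.44 ± 0.750 against 532 ± 115 CPM, log2 fold change -6.90, SE 0.71, adjusted p = 7.2e-06) were far lower in hcp/hcr-. At low oxygen 1354 genes were higher and 1245 lower, 958 of them at least 2-fold, and T449DRAFT_3782 had 25.2 ± 2.59 CPM in the mutant and 5989 ± 1759 CPM in the wild type (log2 fold change -7.90, SE 0.33, adjusted p = 4.55e-09). Both mutant groups at low oxygen include a library in which low alignment quality took over 50% of the reads.

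**Figure D3:**
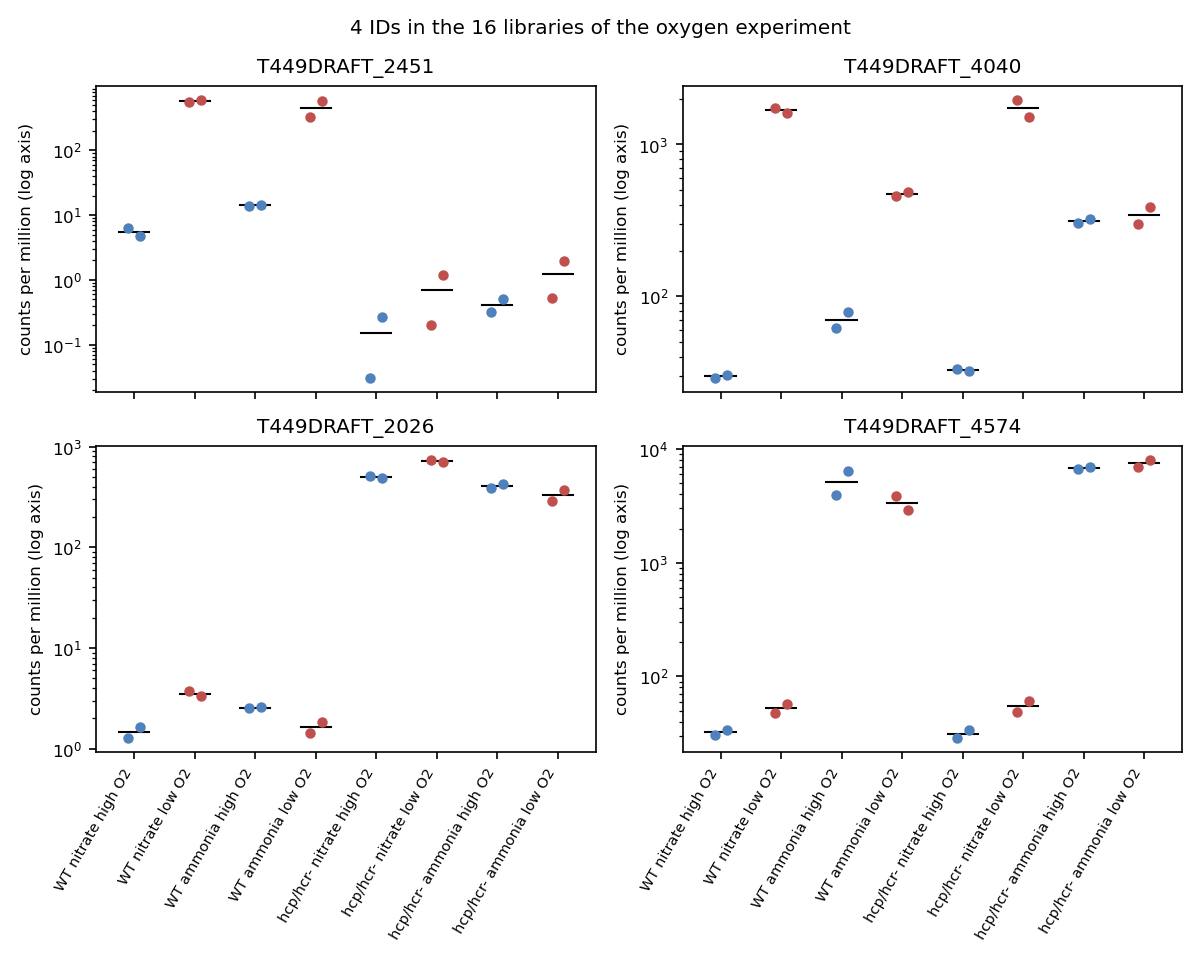
CPM of gene counts without TMM scaling (y axis, log scale) of T449DRAFT_2451, T449DRAFT_4040, T449DRAFT_2026 and T449DRAFT_4574 in the 16 libraries of the oxygen experiment (x axis, 8 groups), where each point is 1 library, blue at high and red at low oxygen, and each line is the mean of 2. T449DRAFT_2451 has 1 to 19 counts in the 8 hcp/hcr- libraries, and T449DRAFT_4040 rose at low oxygen in the 3 comparisons other than hcp/hcr- on ammonia, where its log2 fold change was 0.18 (adjusted p = 0.551).

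Nitrate and ammonia were compared within each genotype and oxygen level of the oxygen experiment. T449DRAFT_2563 stood at 2699.7 ± 73.5 CPM on nitrate and 14.8 ± 1.60 CPM on ammonia in the wild type at high oxygen (log2 fold change 7.51, SE 0.25, adjusted p = 6.1e-10). It was also higher on nitrate in the other 3 conditions, by log2 fold changes of 5.07 (SE 0.22), 5.92 (SE 0.23) and 6.70 (SE 0.24). T449DRAFT_4574 went the other way, with 38.2 ± 2.41 CPM on nitrate and 4851 ± 1523 CPM on ammonia in the wild type at high oxygen (log2 fold change -6.99, SE 0.26, adjusted p = 1.53e-09) and log2 fold changes of -5.75, -7.46 and -6.95 in the other 3. In all 4 conditions together, 16 genes were higher and 16 lower on nitrate by at least 4-fold in each. In the wild type 338 genes were higher and 433 lower on nitrate at high oxygen (230 of the 771 at least 2-fold), and 1119 were higher and 1347 lower at low oxygen (891 at least 2-fold). At low oxygen T449DRAFT_3947 had 2129 ± 36.5 CPM on nitrate and 9.14 ± 0.945 CPM on ammonia, a log2 fold change of 7.86 (SE 0.16, adjusted p = 6.91e-12). In hcp/hcr- 1474 were higher and 1438 lower at high oxygen (1413 at least 2-fold), and 1077 were higher and 1345 lower at low oxygen (840 at least 2-fold). T449DRAFT_4154 led the high-oxygen comparison with 3658 ± 113 against 10.1 ± 0.474 CPM (log2 fold change 8.50, SE 0.50, adjusted p = 6.7e-08), and T449DRAFT_2569 the low-oxygen one with 6516 ± 524 against 41.5 ± 8.16 CPM (log2 fold change 7.31, SE 0.30, adjusted p = 3.64e-09). The high-oxygen values of hcp/hcr- rest on the oxygen label of its ammonia libraries, which is in doubt as said above.

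The share of the 771 wild-type genes at high oxygen that was higher on nitrate, 43.8%, was 52.1% under RLE scaling and 51.3% without the 10 most abundant genes. Which direction had more genes thus depended on the scaling. The count itself was 1989 with only the 2 groups fitted, 465 at equal depth, and 408, 434 and 425 without nitrate replicate 1, nitrate replicate 2 and ammonia replicate 2. The 2422 genes of hcp/hcr- at low oxygen became 1330 with only the 2 groups fitted.

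The nitrogen experiment made the same comparison in 4 further wild-type libraries of 31/32, fitted on their own. T449DRAFT_0966 had 20225 ± 487 CPM on nitrate and 98.8 ± 6.03 CPM on ammonia (log2 fold change 7.68, SE 0.06, adjusted p = 3.16e-17), and T449DRAFT_0965 had 2739 ± 65.7 and 15.1 ± 0.299 CPM (log2 fold change 7.50, SE 0.05, adjusted p = 2.12e-17). T449DRAFT_4394 was lower on nitrate, at 3.26 ± 0.578 against 146 ± 1.79 CPM (log2 fold change -5.50, SE 0.08, adjusted p = 2.66e-15), as was T449DRAFT_4164, at 5.15 ± 0.905 against 152 ± 8.31 CPM (log2 fold change -4.89, SE 0.09, adjusted p = 1.05e-14). In all 1818 genes were higher and 1731 lower on nitrate, of 3954 tested, and 1734 differed at least 2-fold. This fit had 2 residual degrees of freedom, and on simulated counts of its design 7.91% of the calls were false.

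With the labels as given, the effect of nitrate differed between the 2 experiments. In a fit of all 20 wild-type and mutant libraries of 31/32, the wild-type nitrate effect of the oxygen experiment at high oxygen differed from that of the nitrogen experiment in 2846 of 3958 genes (1380 with a higher log2 change in the oxygen experiment and 1466 with a lower one). T449DRAFT_4574 had the most negative difference, -8.62 (SE 0.29, adjusted p = 7.19e-12), and T449DRAFT_3950 the most positive, 7.09 (SE 0.17, adjusted p = 1.49e-13), by the naming rule. Of the 32 genes with differences of at least 4-fold in all 4 nitrogen comparisons of the oxygen experiment, 5 were called in the same direction in the nitrogen experiment and 23 in the opposite one. Across genes the fold changes of the wild type at high oxygen and of the nitrogen experiment had a Pearson r of 0.0239. For the wild type at low oxygen this r was 0.181, and 65.6% of the 2242 genes called in both went the same way.

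In 21/22 the same nitrogen comparison was made in 3 genotypes. In the wild type, 2563531394 had 22750 ± 679 CPM on nitrate and 30.9 ± 1.77 CPM on ammonia (log2 fold change 9.52, SE 0.14, adjusted p = 9.41e-15), and 2563531393 had 5586 ± 12 and 7.70 ± 1.19 CPM (log2 fold change 9.50, SE 0.16, adjusted p = 2.51e-14). On ammonia 2563532862 was the higher one, with 4662 ± 653 against 45.7 ± 9.59 CPM on nitrate (log2 fold change -6.67, SE 0.18, adjusted p = 1.32e-12), and so was 2563532859 (log2 fold change -6.64, SE 0.19, adjusted p = 2.62e-12). There were 1698 genes higher and 1711 lower on nitrate of 4169 tested, and 1569 differed at least 2-fold.

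In qs-, 2563533253 had 3562 ± 16.8 CPM on nitrate and 17.3 ± 3.90 CPM on ammonia (log2 fold change 7.68, SE 0.39, adjusted p = 3.52e-09). In the wild type it was lower on nitrate (log2 fold change -5.37, SE 0.35, adjusted p = 3.76e-08). Both 2563532859 (log2 fold change -7.98, SE 0.20, adjusted p = 2.2e-12) and 2563532862 (-7.70, SE 0.19, adjusted p = 1.53e-12) were lower on nitrate in qs-, as in the wild type. In all 1719 genes were higher and 1769 lower on nitrate in qs-, 1735 of them at least 2-fold. Across genes the fold changes in qs- ran against those of the wild type (Pearson r -0.407), and of 2929 genes called in both, 23.1% went the same way. With the wild-type labels turned these values are 0.407 and 76.9%.

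In tundrinone-, 2563530634 had 398 ± 0.289 CPM on nitrate and 9.62 ± 0.531 CPM on ammonia (log2 fold change 5.37, SE 0.18, adjusted p = 3.12e-10), and 2563530174 had 1636 ± 22.0 and 58.0 ± 1.11 CPM (log2 fold change 4.82, SE 0.10, adjusted p = 1.26e-12). 2563533221 was at 0.498 ± 0.119 CPM on nitrate and 887 ± 79.2 CPM on ammonia (log2 fold change -10.81, SE 0.29, adjusted p = 3.88e-11). There were 1252 genes higher and 1331 lower on nitrate, and 592 differed at least 2-fold. Across genes the fold changes had a Pearson r of -0.197 with those of the wild type and of 0.547 with those of qs-, and 85.8% of the 2311 genes called in both mutants went the same way. Of 2189 genes called in tundrinone- and the wild type, 33.2% went the same way. With the wild-type labels turned, that share is 66.8% and the r with the wild type 0.197. In all 3 genotypes, 3 genes were higher and 9 lower on nitrate by at least 4-fold.

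The difference between genotypes in the nitrate effect was tested directly, with the labels as given. Exchanged nitrate and ammonia labels of the wild type could not be excluded, and all values of these tests rest on them. Values with those labels turned are not given for these tests. For qs- it passed in 3607 genes (1759 with a higher log2 change than in the wild type and 1848 with a lower one), with 2563533253 at 13.06 (SE 0.52, adjusted p = 2.71e-10) and 2563534308 at -14.16 (SE 0.31, adjusted p = 8.61e-13). For tundrinone- it passed in 3285 genes (1610 and 1675), with 2563533253 at 9.13 (SE 0.48, adjusted p = 5.85e-09). 2563531513 differed by -13.03 (SE 0.15, adjusted p = 2.5e-15): its log2 fold change on nitrate was 8.48 in the wild type, 7.40 in qs- and -4.55 in tundrinone-.

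**Figure D4:**
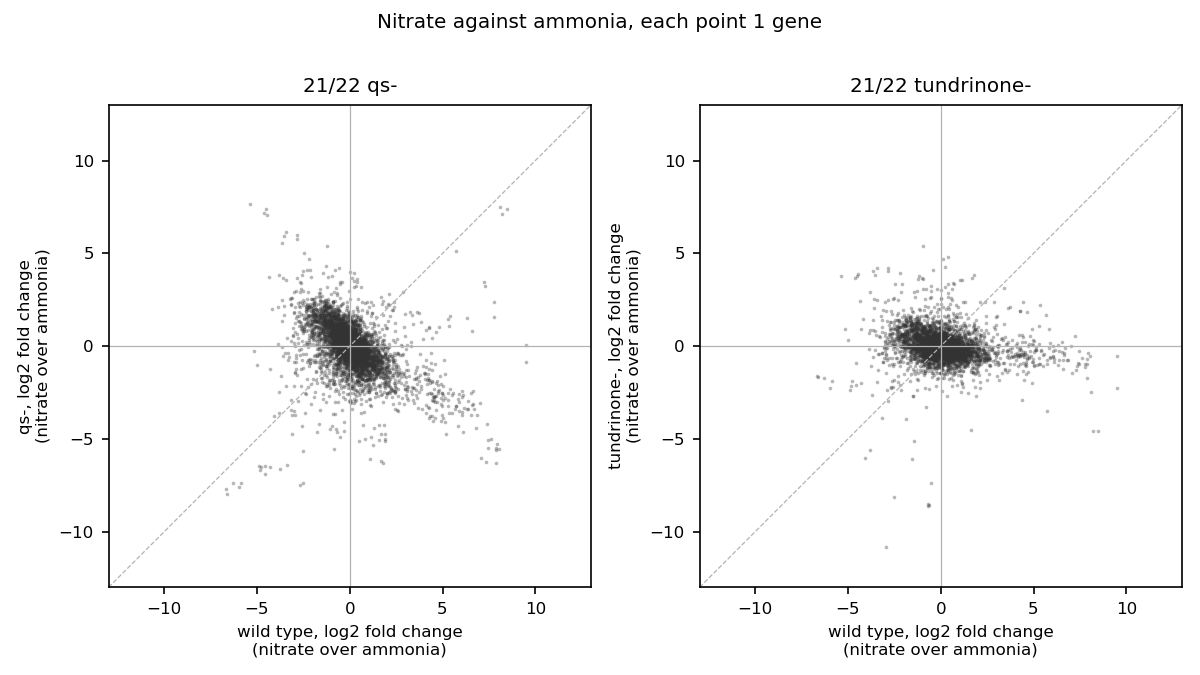
Log2 fold change of nitrate over ammonia in the wild type of 21/22 (x axis) and in qs- (left) or tundrinone- (right) on the y axis, with 1 point for each of the 4169 genes tested and a dashed line where both are equal. The Pearson r across genes is -0.407 for qs- and -0.197 for tundrinone- with the labels as given, and 0.407 and 0.197 with the wild-type labels turned.

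Each 21/22 mutant was then compared with the wild type on each nitrogen source. On nitrate both mutants had more of 2563533253, at 3562 ± 16.8 CPM in qs- and 3034 ± 104 CPM in tundrinone- against 15.5 ± 2.56 CPM in the wild type (log2 fold changes 7.84, SE 0.39, adjusted p = 1.93e-09, and 7.61, SE 0.39, adjusted p = 2.18e-09). 2563533252 was higher in both as well, at 1494 ± 31.7 and 1502 ± 39.1 against 12.7 ± 0.0812 CPM. 2563531393 was lower in both, at 6.70 ± 1.05 CPM in qs- and 2.62 ± 0.145 CPM in tundrinone- against 5586 ± 12 CPM (log2 fold changes -9.70, SE 0.16, adjusted p = 2.39e-14, and -11.05, SE 0.19, adjusted p = 2.14e-14). In qs- 1751 genes were higher and 1819 lower than in the wild type on nitrate, 2037 of them at least 2-fold. In tundrinone- 1691 were higher and 1977 lower, 2279 of them at least 2-fold, and the median over all genes lay at -0.18 log2, or -0.07 under RLE scaling, so changes of that size are not distinct from the scaling.

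With the labels as given, fewer genes differed from the wild type by at least 2-fold on ammonia than on nitrate. In qs-, 2563534308 had 117 ± 8.13 against 2.86 ± 1.27 CPM (log2 fold change 5.35, SE 0.21, adjusted p = 1.18e-09) and 2563530944 had 0.723 ± 0.247 CPM, 137-fold less than the wild type (log2 fold change -7.10, SE 0.18, adjusted p = 7.28e-12). In tundrinone-, 2563531514 had 660.3 ± 66.6 against 10.6 ± 0.761 CPM (log2 fold change 5.96, SE 0.14, adjusted p = 4.79e-12) and 2563532862 had 92.1 ± 4.68 against 4662 ± 653 CPM (log2 fold change -5.66, SE 0.17, adjusted p = 5.57e-11). There were 1534 genes higher and 1539 lower in qs- (770 at least 2-fold), and 1129 higher and 1323 lower in tundrinone- (436 at least 2-fold). Differences of at least 4-fold on both nitrogen sources in one direction, also with the labels as given alone, were seen in 0 genes higher and 2 lower in qs-, and in 1 higher and 26 lower in tundrinone-. With the nitrate and ammonia labels of the wild type turned, a check chosen after the data were seen, the counts at least 2-fold apart were 710 on nitrate and 948 on ammonia in qs-, and 1145 and 1885 in tundrinone-. The order of the nitrogen sources thus rests on those labels. The counts of tundrinone- rest on 9666615 to 20122219 gene counts per library and on the reads that aligned.

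Both mutants were set against the same wild-type libraries, which alone makes their fold changes move together. On nitrate, 1564 genes were higher and 1697 lower in both mutants and 90 were called in opposite directions, where independent lists would share 710 and 863. The Pearson r across genes was 0.950 and the covariance 3.48, and 20 simulations of unchanged mutants against these controls gave a mean r of 0.437, a covariance of 0.00883 and 0 shared calls. On ammonia, 142 genes were higher and 271 lower in both mutants and 1490 were called in opposite directions, where independent lists would share 415 and 488. The r there was -0.253 and the covariance -0.179, against simulated values of 0.466 and 0.00864, with 0.05 shared calls per simulation. The controls were not split, since each part would keep 1 library. The simulated values argue against spread between the control libraries as the source of most of the excess on nitrate. A shift of the whole wild-type group, as exchanged labels would give, is not covered by the simulations and may add to it. Of the covariance on nitrate, 3.47 remained after the simulated value was taken off. The contrast between nitrate and ammonia here rests on the wild-type labels as given, and values with those labels turned are not given for it.

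**Figure D5:**
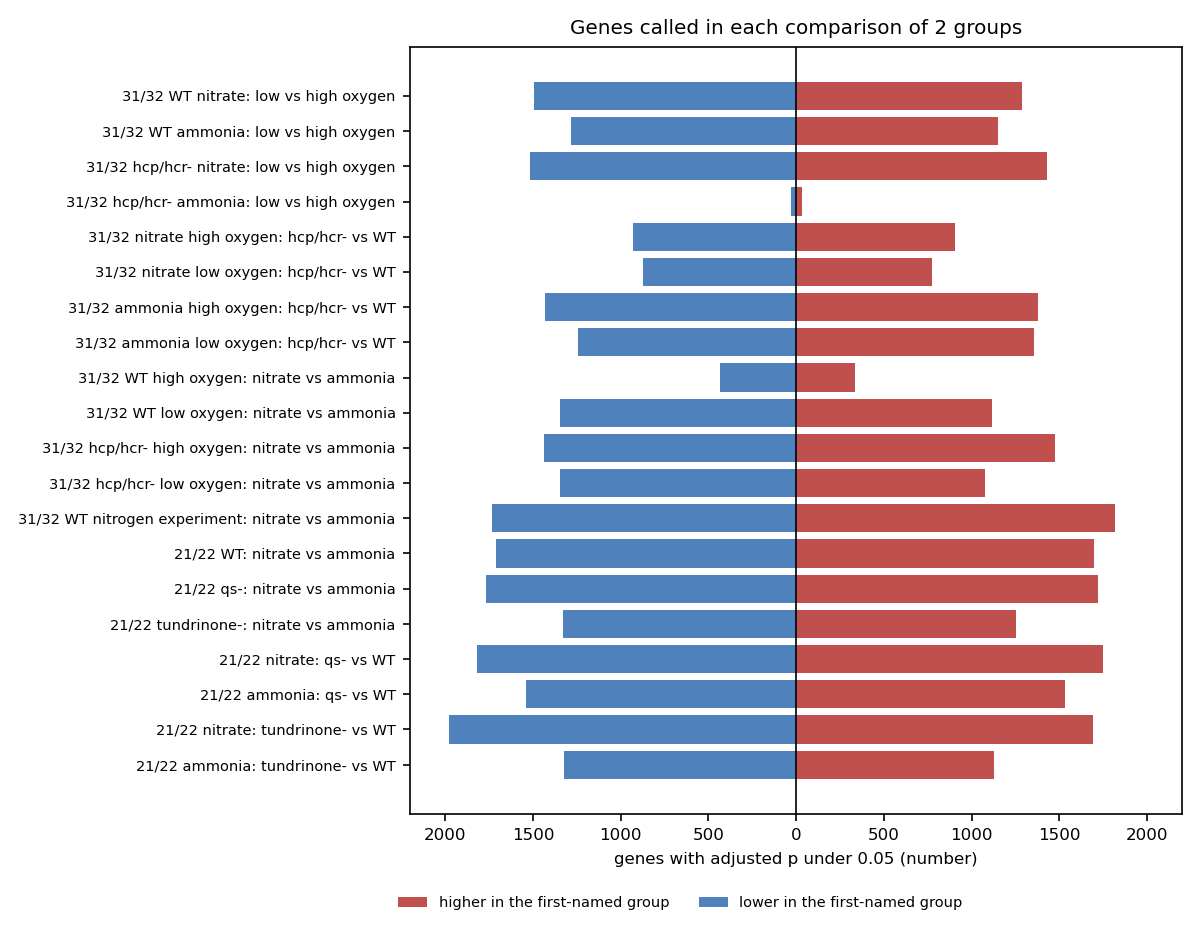
Number of genes with an adjusted p under 0.05 in each comparison of 2 groups (x axis, genes higher in the first-named group to the right in red, lower to the left in blue; y axis, the comparisons). The 31/32 hcp/hcr- comparison of oxygen levels on ammonia has 63 genes, and the other 19 have 771 to 3668.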

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

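The tests of interactions were chosen before the data were examined, and the comparisons of read shares and the tests of explanations, with their bounds, only after the results were seen. For hcp/hcr- on ammonia, the replicate block took the place of depth as a tested explanation, and the tests of a wrong label took the place of earlier ones (r 0.169, then r 0.991 between the means of the mutant's ammonia groups), after those values were seen. A difference between groups in the same effect, tested directly, was found 6 times. In 31/32 the oxygen effect differed between genotypes in 1250 genes on nitrate and in 1863 on ammonia, and between nitrogen sources in 1921 genes of the wild type. The nitrate effect of the wild type, with the labels as given, differed between the 2 experiments in 2846 genes. In 21/22, with the labels as given, it differed from the wild type in 3607 genes in qs- and in 3285 in tundrinone-.

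Reads outside the gene counts also stood apart. Reads not aligned were 43.9% ± 3.40 (SD, n = 2) in tundrinone- on ammonia and 61.3% ± 2.49 on nitrate, above the 0.217% to 3.47% of the other 21/22 libraries. Reads of low alignment quality were 32.5% ± 27.9 in hcp/hcr- on nitrate and 44.9% ± 37.0 on ammonia at low oxygen, against 2.40% to 20.8% in the wild-type libraries of that experiment, and 1 library of each pair carried most of it.

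In hcp/hcr- on ammonia the oxygen levels differed in few genes, with a median absolute log2 fold change of 0.15 against 0.52 in the wild type. A replicate difference shared by the low-oxygen libraries, or depth, is not the whole cause: with a block for it 540 genes were called against 2879 in the wild type, and at equal depth 18 against 1792. A wrong oxygen label on low-oxygen cultures of both replicate numbers is argued against, since the difference between the 2 libraries labelled high oxygen had r -0.15 to -0.10 across genes with those of the 4 low-oxygen groups, which had r 0.34 to 0.81 with each other. A low-oxygen-like state of these libraries is a candidate explanation. It was tested across the 2783 genes called between oxygen levels in the wild type on nitrate. The mutant's difference from the wild type on ammonia at high oxygen had r 0.591 with that oxygen effect (0.3 or more was needed). At low oxygen this r was 0.169. Passing the bound is not particular to such a state: the nitrate minus ammonia difference of hcp/hcr- at low oxygen had r 0.402 with the same effect. A wrong label on 2 libraries from low-oxygen cultures of 1 number cannot be told apart from such a state, since both had r 0.993 with low oxygen replicate 1, between the replicates of the low-oxygen groups (0.973 to 0.990) and of the high-oxygen groups (0.997 to 0.998). Every oxygen comparison shared the collection times of 1 h and 24 h. On that schedule 2432 genes were called in the wild type on ammonia and 2947 in hcp/hcr- on nitrate. These counts argue against the schedule alone as the cause. An effect of the deletion, and a departure from the schedule in these cultures, stay open.

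The nitrate effect on 31/32 wild type differed in direction and size between the 2 experiments: 704 genes were called both at high oxygen in the oxygen experiment and in the nitrogen experiment, and 46.2% of them went the same way. The 32 genes that differed at least 4-fold in all 4 nitrogen comparisons of the oxygen experiment had a median of -1.03 in the nitrogen experiment. It was signed by their direction in the oxygen experiment (quartiles -1.30 and -0.06) and fell short of -2, the bound set for exchanged nitrogen labels. The bound was first a median of -1, and under it this exchange would have stayed open. That bound was changed after the values were seen. Of the 32 genes, 23 were called in the opposite direction (0 at least 4-fold) and 5 in the same one (1 at least 4-fold). Sizes can differ between experiments, so this test cannot exclude the exchange. A low-oxygen-like state of the nitrate libraries of the nitrogen experiment is a candidate explanation. Their difference from ammonia had r 0.619 across genes with the oxygen effect of the wild type on nitrate, where 0.3 or more was needed. Passing that bound is not particular to such a state. The nitrate minus ammonia difference of hcp/hcr- at low oxygen had r 0.402 with the same effect. Both groups of that comparison were labelled low oxygen, so the r alone cannot decide the question. The experiments may also differ in culture conditions that the protocol in the labels does not describe, and this stays open.

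In 21/22 nitrate and ammonia moved many genes in opposite directions in the wild type and qs-, with 23.1% of the 2929 genes called in both going the same way. Exchanged labels on the qs- libraries are argued against by the 25 genes that differed at least 4-fold in one direction in the wild type and tundrinone-, whose signed median was 1.82 in qs- (quartiles 0.65 and 3.75). That argument takes the labels of the wild type and tundrinone- as right. The test of the wild-type labels, given below, likewise takes the labels of both mutants as right. An exchange on the tundrinone- libraries was not among the explanations tested. The 49 genes at least 4-fold apart in one direction in the wild type and qs- had a signed median of 0.86 in tundrinone- (quartiles -0.30 and 1.97). Of these, 29 were called in the same direction there and 14 in the opposite one. The 68 genes at least 4-fold apart in both mutants had a signed median of -0.65 in the wild type with quartiles of -2.47 and 0.89. There 40 of the 68 were called in the opposite direction (22 at least 4-fold) and 22 in the same one (12 at least 4-fold). Exchanged labels on the wild-type libraries thus cannot be told apart from an effect of the genotypes. Under the bound used first (a median of -1) this exchange would have been excluded; with these labels turned, 76.9% of the 2929 genes go the same way, and the mutants' genes at least 2-fold from the wild type number 710 (qs-) and 1145 (tundrinone-) on nitrate in place of 2037 and 2279, and 948 and 1885 on ammonia in place of 770 and 436. An effect of quorum sensing on the response to nitrate stays open and was not tested apart from these labels.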

How the results depend on the processing

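Equal depth, a block for the replicate number in low oxygen, and leaving out the 2 libraries of low alignment quality or the tundrinone- libraries were chosen after the data were seen, the other alternatives before the data were examined. Of 333 alternative counts, 309 lay within 1.5 times the reported one. This held for 26 of 26 counts each under RLE scaling, no filter, removal of the 10 most abundant genes and a replicate block, for 25 of 26 with DESeq2, 14 of 19 with only the 2 groups, 17 of 24 at equal depth, 14 of 15 without the 2 libraries, 9 of 11 with the block in low oxygen, 5 of 5 without tundrinone- and 1 of 1 with all 31/32 libraries. Of 1331 values of named IDs, 1302 kept their direction and call, 29 kept their direction with an adjusted p of 0.05 or more, and 0 turned. In 15 of 26 comparisons and interactions, whether more genes were higher or lower changed between TMM, RLE and removal of the 10 most abundant genes. The oxygen comparison in hcp/hcr- on ammonia (63 genes) had 212 with DESeq2, 35 without the 2 libraries, 18 at equal depth, 540 with the block in low oxygen, 2 to 280 with 1 library left out, and 0 by edgeR with only the 2 groups (592 at an unadjusted p under 0.05). With only the 2 groups, hcp/hcr- against the wild type on nitrate had 3064 genes at high and 672 at low oxygen, nitrate against ammonia 1989 in the wild type at high oxygen and 1330 in hcp/hcr- at low oxygen. At equal depth hcp/hcr- against the wild type on nitrate had 1166 at high and 1070 at low oxygen, nitrate against ammonia in the wild type at high oxygen 465, and the interactions 662 (genotype by oxygen, nitrate), 1230 (ammonia) and 1187 (nitrogen by oxygen). The interaction of genotype by oxygen on nitrate (1250 genes) had 1976 with the block in low oxygen and 833 to 1564 with 1 library left out, and nitrate against ammonia in the wild type at high oxygen (771) had 408 to 530. Fewer reads lower the counts at equal depth by construction; for the others the cause was not tested. Replicate numbers did not pair the samples in general: 6 of 28 pairs of groups in the oxygen experiment had replicate differences with r over 0.1, and 3 of 15 in 21/22. In 21/22 this r ran from -0.30 to 0.39, with the highest between tundrinone- and the wild type on ammonia. The 6 pairs of the oxygen experiment were all 6 between the 4 low-oxygen groups (r 0.34 to 0.81). The low-oxygen libraries thus shared a difference by replicate number, which the main fits left out. The tests of gene lists, and their repeat with an estimated correlation, were not run because no product names come with the IDs. Depth limits the counts of the oxygen experiment, where 7 of 15 moved by over 1.5 times at equal depth, and 0 of the 9 in 21/22 did.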

Other observations

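The tests in this part were chosen only after the results were seen. In 46 of 52 lists of IDs that differed at least 4-fold in one direction, 1 per comparison or interaction and direction, the longest run of consecutive numbers was longer than in every shuffle of the IDs. The other 6 were both lists of hcp/hcr- on ammonia between oxygen levels, which held 0 IDs, the higher IDs of the wild type on ammonia at low oxygen, and the lower IDs of the 3 interactions within the oxygen experiment; the last 4 had longest runs of 3, against at most 3. The lists below were chosen for their long runs. Among the 4-fold higher IDs of the wild type of 31/32 on nitrate at low oxygen, the longest run held 11 consecutive IDs, against at most 4 in 1000 shuffles, and among the lower IDs 5, against at most 4. In hcp/hcr- against the wild type on nitrate at high oxygen, the longest runs held 15 higher and 17 lower IDs, against at most 3. In 21/22 the longest run of higher IDs on nitrate in the wild type held 20, against at most 5. Against the wild type on nitrate, the longest runs of lower IDs held 21 in qs- and 27 in tundrinone-, against at most 7 and 9. The files do not state that consecutive numbers are neighbours on the genome.

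Group means of log2 CPM were also compared across genes, which are not independent replicates. On nitrate qs- and tundrinone- had r 0.967 with each other and 0.668 and 0.630 with the wild type. The wild type on nitrate had r 0.857 with qs- on ammonia and 0.717 with tundrinone- on ammonia. The wild type on ammonia had 0.905 with qs- on nitrate, 0.902 with qs- on ammonia, 0.892 with tundrinone- on nitrate and 0.944 with tundrinone- on ammonia. In 31/32 the ammonia group of the nitrogen experiment had its highest r with hcp/hcr- on nitrate at high oxygen in the oxygen experiment (0.947), and 0.935 with the wild type on ammonia at high oxygen. The nitrate group had its highest r with hcp/hcr- on ammonia at low oxygen (0.858), and 0.769 with the wild type on nitrate at high oxygen and 0.838 at low oxygen.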
